A study of Haemaphysalis longicornis with 21 samples.

How the data were processed

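The material was whole bodies of adult, unfed Haemaphysalis longicornis, in 21 libraries of 7 groups with 3 libraries each, per the labels. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with an NEBNext Ultra RNA kit and sequenced on an Illumina instrument. The control was 50% ethanol, and the treatments were C. citratus essential oil and citronellal at 10, 15 and 20 mg/mL. The labels number the replicates 1 to 3 within a group and do not say whether they came from separate ticks or pools, so p-values measure the spread between these libraries, which may be technical. They give no exposure time, sequencing batch or date.

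Per the file headers, the authors deposited estimated counts per unigene for each library. Of the cells, 9.04% are not whole numbers, so all were rounded before testing. Unigenes are clustered transcripts named Cluster-n.m. The assembler, the aligner, the counting tool and the strand setting are not given in the sources used here. Near-identical copies, members of multigene families and fragments of a single transcript can share or split reads under such counting, and reads of overlapping antisense transcripts cannot be told apart without strand. Results for single unigenes of families such as P450, acetylcholinesterase or vitellogenin are uncertain to that extent, and a list's count is a count of unigenes, not of genes. The table holds 166710 unigenes, 288 of them with no count in any library. Names are the best matches the authors gave: 21530 unigenes have a Swiss-Prot description, 35980 an NR description and 40619 a Pfam description.

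Per the file headers, the authors also deposited log2 fold changes and q-values for their comparisons. These were made with DESeq2 and called at an unadjusted p-value under 0.05, per the file headers. A quality table deposited by the authors gives counts of read pairs before and after filtering and the GC percent of the filtered reads. Its header is shifted by 1 column against its values, and the columns were read by their values. Columns of FPKM (21) and of other quality measures (5) were not used, nor were the authors' group means of FPKM.

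Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Unigenes were kept by filterByExpr with the groups as design, which left 61967 of 166710. Libraries were scaled by TMM. All 21 libraries entered a single model with a coefficient per group (14 residual degrees of freedom, common biological coefficient of variation 48.6%), fitted by glmQLFit with robust dispersion and tested by glmQLFTest, edgeR's quasi-likelihood test. P-values were adjusted by Benjamini-Hochberg over the unigenes of a comparison, and a unigene was called at an adjusted p under 0.05 with no minimum fold change. There were 14 comparisons: the mean of the 3 oil groups and the mean of the 3 citronellal groups against control, these means against each other, each of the 6 treated groups against control, the oil against citronellal at each concentration, and 20 against 10 mg/mL of each compound.

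Named unigenes were those called, with a mean CPM of at least 5 over all libraries, the same direction at all 3 concentrations, and an informative Swiss-Prot or else NR name. The 12 with the largest rise and the 12 with the largest fall were taken for each compound against control, and 8 and 8 for the oil against citronellal, with 1 unigene per name. For each list and compound, the called member with the smallest adjusted p in each direction was added. The 28 gene lists were made by matching words in the Swiss-Prot, NR and Pfam descriptions. They cover enzymes and transporters that act on foreign compounds, stress and proteasome, ion channels and receptors, cuticle, muscle, yolk and salivary families, proteases and their inhibitors, immune effectors, iron handling, mitochondria, translation, fatty acids, cell death, and histones and DNA replication. The 27 lists with at least 5 tested members were tested. As any description may match, some members carry another name.

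Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Camera compares a list with all other unigenes, of which many have no description and could not be on a list. Fry asks whether a list moves, on balance, one way, and does not compare it with other genes. Library properties were compared by two-sided exact permutation tests. Intervals of differences are 95% intervals from the fitted model. For the shared controls, 20 sets of unchanged groups were simulated. Pfam domains with at least 20 tested unigenes were compared by Fisher's exact test among tested unigenes with a domain.

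The groups, comparisons, lists, naming rule and alternatives were fixed before the data were examined, except for 6 alternatives that were chosen after seeing the data: without citronellal 20 mg/mL replicate 1, without that library and citronellal 15 mg/mL replicate 1, without rRNA unigenes, with separate control libraries for the oil and for citronellal, and camera among the 31818 described unigenes alone, with the preset and with an estimated correlation. The Pfam tests were also chosen after seeing the data. The other alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, a mean CPM (no TMM factor) of at least 1, an adjusted p under 0.01 with an absolute log2 fold change of at least 1, only the groups compared in the fit, the replicate number as a block, lists from Swiss-Prot names alone, and each library left out in turn. Tables and plots used pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

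The procedure was tested on simulated data drawn from the real means and library sizes, with 200 of 61967 unigenes changed. For the oil mean against control it called 2% of unigenes changed 2-fold and 32% of those changed 4-fold, with median estimated log2 fold changes of 0.96 and 2.08 and 1 false call. For the oil at 20 mg/mL against control it called 0% and 14%. Camera called the changed list and 0 of 20 unchanged ones, but unigenes were drawn independently, so correlated lists stay untested. In the NR matches, no unigene matched the listed bacterial genera or vertebrate hosts, and 4 matched Babesia (9.16e-05% of control and 3.89e-05% of treated counts). No pair of replicates of a group had counts that agreed within sampling noise, as 1 library under both names would (chi-square per unigene 15.7 to 124.5). Each library was counted as 1 replicate. Cluster names could not be paired with a reference gene table, and genome positions are not given.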

Results

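Whole-body transcriptomes of adult, unfed Haemaphysalis longicornis, the Asian longhorned tick, were measured by RNA sequencing in 21 libraries. There were 7 groups of 3 libraries. The control group received 50% ethanol, and the others received C. citratus essential oil, a plant oil that is a mixture of compounds, or citronellal, a monoterpenoid aldehyde, each at 10, 15 or 20 mg/mL. The question asked was which transcripts differ from control under each treatment, and whether the oil and citronellal differ at the same concentration. Total counts were 16991745 to 17240128 in the control libraries and 15139536 to 16423063 in the treated ones. Of 166710 unigenes, the transcripts assembled without a genome, 61967 had enough counts to be tested, and 18905 of these carried a protein name. Levels are given as CPM, counts scaled to a library's tested counts times its TMM factor, with the SD over libraries. For control n = 3, and for the 3 concentrations of a compound combined n = 9. Log2 fold changes and adjusted p-values come from edgeR's quasi-likelihood test. The largest rises and falls were ranked among called unigenes with a protein name, a mean of at least 5 CPM over all libraries and the same direction at all 3 concentrations.

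Control and treated libraries also differed in general properties of the reads. GC content of the filtered reads was 53.3% ± 0.445 (SD, n = 3) in control and 50.5% ± 1.0 (SD, n = 18) in treated libraries, and all 18 treated libraries lay below all controls (two-sided exact permutation test, p = 0.000752, the smallest that 1330 splits can give, adjusted p = 0.00226 over 9 measures). The share of counts on unigenes with a protein name was 66.2% ± 1.25 in control and 59.7% ± 3.27 in treated libraries (exact permutation test, adjusted p = 0.0108, lower in 18 of 18). The share on unigenes with a mitochondrial match, rRNA and mRNA, was 4.39% ± 0.606 and 6.24% ± 2.03 (exact permutation test, adjusted p = 0.184), and lay above all controls in 14 of 18 treated libraries. Citronellal 20 mg/mL replicate 1 stood apart, with 72593 unigenes counted against 95152 to 112448 in the other libraries, 5.56% nuclear rRNA against at most 0.616%, and 11.9% mitochondrial counts against at most 9.45%. The highest of the latter was citronellal 15 mg/mL replicate 1.

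**Figure D1:**
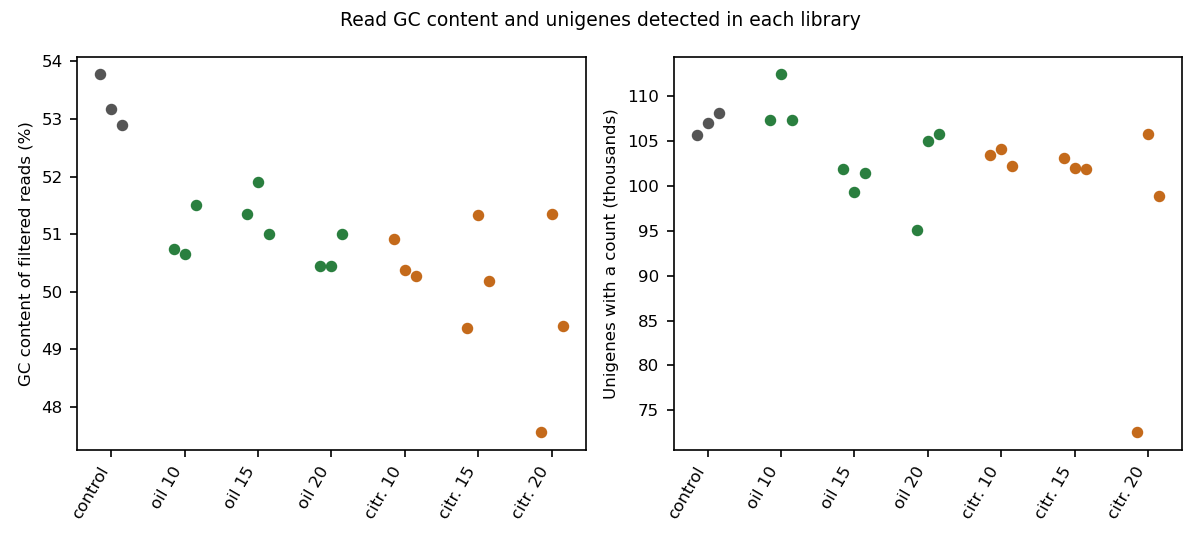
GC content of the filtered reads in percent (left) and number of unigenes with a count (right), 1 point per library, by group. All 18 treated libraries lie below the 3 controls in GC content, and citronellal 20 mg/mL replicate 1 has the fewest unigenes counted, 72593.

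Under the oil, transcripts for lipid synthesis, yolk and cuticle were among those that fell most. Fatty acid synthase (Cluster-40802.40647), the enzyme that builds fatty acids, fell from 720.4 ± 475 to 45.2 ± 46.8 CPM (log2 fold change -4.18, SE 0.63, adjusted p = 0.00103). Vitellogenin-2 (Cluster-40802.6912), a yolk protein precursor, fell from 28.4 ± 18.8 to 1.41 ± 1.04 CPM (log2 fold change -4.60, SE 0.42, adjusted p = 3.01e-06), and vitellogenin-1 (Cluster-40802.46966) fell from 54.7 ± 40.6 to 4.08 ± 4.07 CPM. A putative cuticular protein (Cluster-40802.13925) fell from 40.4 ± 29 to 1.40 ± 0.936 CPM (log2 fold change -5.01, SE 0.44, adjusted p = 2.63e-06), and an acetylcholinesterase (Cluster-40802.84389), by name an enzyme that breaks down acetylcholine, fell from 28.1 ± 13.6 to 1.90 ± 1.01 CPM (log2 fold change -3.99, SE 0.47, adjusted p = 5.26e-05). Among the rises, an intracellular cystatin (Cluster-40802.74173) went from 6.89 ± 1.65 to 25 ± 8.22 CPM (log2 fold change 1.80, SE 0.28, adjusted p = 0.000662). Without control replicate 1 the log2 fold change was -3.43 for vitellogenin-1, where it was -4.10 with all libraries, and -4.27 for the cuticular protein.

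The 12 largest falls also held salivary cystatin-L (Cluster-40802.60419, log2 fold change -3.89), another cystatin (Cluster-40802.60418, -4.53), a Kunitz domain protein (Cluster-40802.24685, -4.30), leukocyte elastase inhibitor C (Cluster-40802.81841, -4.09) and serine protease inhibitor swm-1 (Cluster-40802.64436, -3.98). The serpin and Kunitz inhibitor list, which also takes cystatins, did not pass under the oil (camera adjusted p = 0.122). An insulin-like growth factor binding protein-related protein (Cluster-40802.40549) fell from 61.6 ± 11.3 to 3.62 ± 2.19 CPM (adjusted p = 8.75e-07), and an endonuclease-reverse transcriptase (Cluster-40802.28191) had a log2 fold change of -3.86. All 12 kept their call without any single library, but the log2 fold change was -3.70 for the Kunitz domain protein without control replicate 2 and -3.30 for swm-1 without control replicate 1. Of the 34 named falls, 33 had all 9 oil libraries below all controls, as had 17 of 33 named rises in the other direction. Chance gives this for 0.455% of unigenes in each direction, although these unigenes were chosen by the test. Of the 12 largest rises, 3 kept their call without any single library: a pogo transposable element protein (Cluster-40802.11590, from 1.49 ± 0.393 to 13.6 ± 12.6 CPM, adjusted p = 0.00374), a FYVE and coiled-coil domain protein (Cluster-40802.47869, from 29.6 ± 3.59 to 118 ± 58 CPM, adjusted p = 0.00442) and the intracellular cystatin. AV422 (Cluster-40802.55432) rose from 3.08 ± 0.708 to 22.8 ± 15.1 CPM (adjusted p = 0.0073, but 0.0511 without control replicate 1). The other 8, with log2 fold changes from 1.94 to 2.98, lost their call without 2 to 9 of the 12 libraries, and their highest adjusted p, each without a control library, ran from 0.058 to 0.172. They were elongation factor 2 (log2 fold change 2.98, but 6.23 without control replicate 3), a secreted salivary protein, venom protein 302, a GGY domain protein, a cytochrome P450 of family 2, a retrovirus-related Pol polyprotein, a P transposase and folylpolyglutamate synthase.

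The mean of the 3 oil concentrations against control gave 5510 called unigenes, 2451 higher and 3059 lower (302 and 1751 among those with a protein name). The count was 1713 at an adjusted p under 0.01 with at least a 2-fold change, 9073 with citronellal libraries left out of the fit, and 9079 without citronellal 20 mg/mL replicate 1 and 15 mg/mL replicate 1. It was 1498, 2385 and 3495 without control replicates 1, 2 and 3.

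Lists of lipid handling and reproduction were called lower under the oil. Of the fatty acid metabolism unigenes 81 of 311 fell and 2 rose (109 and 5 adjusted over the list alone), with a median log2 fold change of -0.75 (camera adjusted p = 3.4e-14, and adjusted p = 0.0599 with an estimated correlation). An elongase of very long chain fatty acids (Cluster-40802.106384) fell from 10.9 ± 7.56 to 0.624 ± 0.295 CPM (log2 fold change -4.17, and -3.51 without control replicate 1), while elongase 4 (Cluster-40802.29737) rose (log2 fold change 0.69, adjusted p = 0.00607, but 0.0575 without control replicate 1). Of the vitellogenin and yolk unigenes 21 of 36 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -2.64 (camera adjusted p = 1e-20, and adjusted p = 0.0599 with an estimated correlation). Camera called 15 of the 27 lists, 14 of them lower, and none of these calls held with an estimated correlation. Of the 31818 tested unigenes with any description 7.21% were lower, and against these alone camera called 13. The oil libraries of these comparisons also had the lower GC content and named share of counts given above.

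Lists of enzymes that act on foreign compounds were called lower under the oil. Cytochrome P450 4V2 (Cluster-40802.79228), a monooxygenase by name, fell from 23.9 ± 11.5 to 3.48 ± 0.484 CPM (log2 fold change -2.79, SE 0.23, adjusted p = 9.57e-07). Microsomal glutathione S-transferase 3 (Cluster-40802.108967) fell from 7.98 ± 1.60 to 1.15 ± 0.451 CPM, and a mitochondrial aldehyde dehydrogenase (Cluster-40802.74810) fell from 73.2 ± 7.21 to 17.8 ± 6.80 CPM. Of the cytochrome P450 unigenes 41 of 380 fell and 4 rose (43 and 5 adjusted over the list alone), and of the glutathione S-transferase unigenes 11 of 63 fell and 1 rose (17 and 3 adjusted over the list alone). Their camera adjusted p = 3.78e-07 and 0.00138, and adjusted p = 0.355 and 0.331 with an estimated correlation. Among carboxylesterase and cholinesterase unigenes 30 of 93 fell and 2 rose (34 and 2 adjusted over the list alone), and among sulfotransferase unigenes 15 of 157 fell and 0 rose (20 and 0 adjusted over the list alone). The lists' camera adjusted p = 6.5e-15 and 6.32e-05, and adjusted p = 0.0599 and 0.355 with an estimated correlation. For the aldehyde and alcohol dehydrogenase list 25 of 126 fell and 2 rose (34 and 4 adjusted over the list alone). Camera gave adjusted p = 3.25e-06, and adjusted p = 0.207 with an estimated correlation. The fall with the smallest adjusted p among sulfotransferases was a heparan-sulfate 6-O-sulfotransferase (Cluster-40802.45847, log2 fold change -1.34), which by name modifies heparan chains and not small foreign compounds. No unigene of the table used matched the UDP-glycosyltransferase list. ABC transporters had 23 lower and 4 higher of 313 (23 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0589), although ABC transporter C family member 11 (Cluster-40802.1261) fell (log2 fold change -2.89, adjusted p = 0.000142).

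Nerve and tissue lists were also called lower under the oil, TRP channels excepted. Glutamate receptor kainate 3 (Cluster-40802.14072), by name a channel opened by glutamate, fell from 26.6 ± 2.64 to 3.31 ± 1.26 CPM (log2 fold change -3.0, SE 0.33, adjusted p = 2.43e-05). Muscarinic acetylcholine receptor DM1 (Cluster-40802.25865) fell from 8.03 ± 3.71 to 1.74 ± 0.573 CPM (adjusted p = 0.00363, but 0.0571 without control replicate 1). Among ligand-gated ion channel unigenes 11 of 61 fell and 2 rose (15 and 3 adjusted over the list alone), and among voltage-gated ion channel unigenes 8 of 40 fell and 1 rose (15 and 3 adjusted over the list alone). The lists' camera adjusted p = 0.000164 and 0.00152, and adjusted p = 0.314 and 0.224 with an estimated correlation. For the monoamine and muscarinic receptor list 5 of 23 fell and 1 rose (7 and 2 adjusted over the list alone). Camera gave adjusted p = 0.0288, and adjusted p = 0.355 with an estimated correlation. TRP channels had 0 lower and 0 higher of 8 (0 and 0 adjusted over the list alone) and did not pass (camera adjusted p = 0.706). Myosin-16 (Cluster-40802.70917) fell from 20.9 ± 3.43 to 5.56 ± 2.28 CPM. Cathepsin B (Cluster-40802.49351), a cysteine protease, fell from 119.7 ± 66.8 to 15.6 ± 4.70 CPM. For the cuticle protein and chitin metabolism list 40 of 207 fell and 3 rose (46 and 6 adjusted over the list alone), and for the muscle contractile protein list 12 of 97 fell and 1 rose (14 and 1 adjusted over the list alone). Camera gave adjusted p = 1.08e-07 and 5.22e-05, and adjusted p = 0.119 and 0.331 with an estimated correlation. In the salivary protein families list 56 of 418 fell and 2 rose (61 and 7 adjusted over the list alone), and in the cathepsin and legumain (midgut proteases) list 4 of 35 fell and 1 rose (5 and 1 adjusted over the list alone). By camera, adjusted p = 9.25e-05 and 0.0161, and adjusted p = 0.257 and 0.355 with an estimated correlation. Against described unigenes alone the cathepsin list and the monoamine and muscarinic receptor list did not pass (camera adjusted p = 0.124 and 0.148).

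Cytosolic ribosomal proteins were the list called higher under the oil: 2 of 154 fell and 8 rose (1 and 5 adjusted over the list alone), with a median log2 fold change of 0.33 (camera adjusted p = 1.83e-06, and adjusted p = 0.511 with an estimated correlation). Against that direction, 60S ribosomal protein L6 (Cluster-40802.52130) fell from 97.8 ± 16.6 to 23.2 ± 20.4 CPM (log2 fold change -2.38, SE 0.36, adjusted p = 0.000659). The other lists did not pass camera, but fry, which asks whether a list moves one way, called the antioxidant, mitochondrial and ABC lists lower (adjusted p = 0.0075, 0.000432 and 0.0372) and did not call the ribosomal list (adjusted p = 0.134). Heat shock proteins had 15 lower and 7 higher of 128 (17 and 9 adjusted over the list alone), camera adjusted p = 0.585, and within them a small heat shock protein (Cluster-40802.56614) rose from 60.5 ± 7.82 to 155 ± 89.9 CPM in 7 of 9 libraries (adjusted p = 0.00443, but 0.051 without control replicate 1) while the small heat shock protein lethal(2)essential for life (Cluster-40802.52669) fell from 347 ± 55.4 to 81 ± 47 CPM. Antioxidant enzymes had 16 lower and 4 higher of 109 (21 and 5 adjusted over the list alone), camera adjusted p = 0.0811, and Cu-Zn superoxide dismutase (Cluster-40802.52850) fell from 394 ± 88 to 88.6 ± 46.8 CPM. The proteasome list had 8 lower and 3 higher of 139 (8 and 3 adjusted over the list alone), camera adjusted p = 0.924. Apoptosis and autophagy unigenes had 6 lower and 4 higher of 189 (6 and 3 adjusted over the list alone), camera adjusted p = 0.629. Serpins and Kunitz inhibitors had 20 lower and 8 higher of 218 (23 and 8 adjusted over the list alone), camera adjusted p = 0.122. Defensins and immune effectors had 8 lower and 5 higher of 194 (7 and 5 adjusted over the list alone), camera adjusted p = 0.924, with Toll-like receptor 3 (Cluster-40802.60450) among the falls (log2 fold change -3.0). Ferritin and heme handling had 1 lower and 0 higher of 17 (1 and 0 adjusted over the list alone), camera adjusted p = 0.924. The mitochondrial respiratory chain had 31 lower and 10 higher of 360 (36 and 12 adjusted over the list alone), camera adjusted p = 0.176, and aminoacyl-tRNA synthetases had 2 lower and 4 higher of 110 (2 and 0 adjusted over the list alone), camera adjusted p = 0.629. Histones and DNA replication had 4 lower and 1 higher of 72 (4 and 1 adjusted over the list alone), camera adjusted p = 0.43. Median, mean and camera's direction differed in sign under the oil for the proteasome, ferritin and apoptosis lists. Some members called under a list's name do something else: a retrovirus-related Pol polyprotein (Cluster-40802.22829) fell in the proteasome list, a putative ribonuclease H (Cluster-40802.91238) fell in the apoptosis list, and a unigene named acetylcholinesterase (Cluster-40802.69684) fell in the histone list. Of the called rises, an ADP-ribosylation factor-like protein (Cluster-40802.67413) stood in the dehydrogenase list, an AC transposase (Cluster-40802.86470) in the antioxidant list and the nuclease HARBI1 (Cluster-40802.39137) in the immune list. The first lost its call without any single control library or oil 20 mg/mL replicate 1 (adjusted p up to 0.102), the second without control replicate 1 or 2 (up to 0.0943) and HARBI1 without control replicate 1 (0.0543).

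Under citronellal, fatty acid synthase (Cluster-40802.40647) showed the largest fall among the ranked transcripts, from 720.4 ± 475 to 12.3 ± 9.16 CPM (log2 fold change -6.12, SE 0.66, adjusted p = 3.07e-05). The putative cuticular protein (Cluster-40802.13925) fell from 40.4 ± 29 to 1.23 ± 0.736 CPM (log2 fold change -5.12, SE 0.44, adjusted p = 1.41e-06). Arginine kinase (Cluster-40802.43974), which stores energy as phosphoarginine, fell from 105 ± 13 to 4.45 ± 3.25 CPM (log2 fold change -4.62, SE 0.51, adjusted p = 2.49e-05). Vitellogenin-B (Cluster-40802.75567) fell from 46.8 ± 8.77 to 2.77 ± 2.53 CPM and retinol dehydrogenase 13 (Cluster-40802.15113) fell from 64.3 ± 13.7 to 4.11 ± 3.08 CPM. Among the rises, microplusin (Cluster-40802.64357), an antimicrobial peptide, went from 12.2 ± 2.54 to 59.6 ± 62.2 CPM (log2 fold change 2.0, SE 0.46, adjusted p = 0.00565), and a calcium permeable stress-gated cation channel (Cluster-40802.34886) went from 3.73 ± 1.29 to 12.5 ± 3.50 CPM (log2 fold change 1.72, SE 0.29, adjusted p = 0.000512). Citronellal 20 mg/mL replicate 1 held 222 CPM of microplusin, and the other 8 citronellal libraries averaged 39.4 ± 14 CPM. The TMM factor of that library, 0.652, was the lowest of all and raises its CPM against an unscaled total. The log2 fold change of the cuticular protein was -4.38 without control replicate 1, and that of vitellogenin-B went from -4.08 to -4.89 without citronellal 15 mg/mL replicate 2.

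The other largest falls under citronellal were a PDZ domain protein (Cluster-40802.61259, log2 fold change -4.27), a serine-rich adhesin (Cluster-40802.46603, -4.19), a serine protease inhibitor (Cluster-40802.34256, -4.16), a protein named after MamJ (Cluster-40802.66761, -4.16), a Kunitz domain protein (Cluster-40802.24685, -4.12), a cuticle protein (Cluster-40802.55240, -4.12) and a secreted mucin (Cluster-40802.74843, -4.11). All 36 named falls had all 9 citronellal libraries below all controls and 26 of 34 named rises had them above, where chance gives 0.455% in each direction for unigenes that, unlike these, were not chosen by the test. Of these falls 35 kept their call without any single library, and the TRP-gamma protein (Cluster-40802.45824) lost it without control replicate 1 (adjusted p = 0.0704). The Kunitz domain protein had a log2 fold change of -3.54 without control replicate 2, and the mucin had -5.34 without citronellal 15 mg/mL replicate 2. Of the 12 largest rises, microplusin and the stress-gated channel kept theirs. Elongation factor 2 (Cluster-40802.56350) rose from 0.648 ± 1.02 to 7.15 ± 4.15 CPM (log2 fold change 3.43, but 6.67 without control replicate 3, adjusted p = 0.0106, but 0.0599 without control replicate 2), and an RNA exonuclease 1 homolog (Cluster-40802.21948) had a log2 fold change of 1.85 (adjusted p = 0.0128, but 0.0866 without control replicate 2). The other 8, with log2 fold changes from 1.72 to 2.36, lost their call without 2 to 9 of the 12 libraries, and their highest adjusted p, each without a control library, ran from 0.0713 to 0.195. They were a Kunitz inhibitor named bitisilin, 60S ribosomal protein L7a (log2 fold change 2.32, and 1.73 without control replicate 2), a pair of zinc finger proteins, initiation factor IF-2, a serum amyloid A-like protein, a jockey element polymerase and the nuclease HARBI1 (1.72, and 2.58 without control replicate 3).

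Citronellal against control gave 13146 called unigenes, 5874 higher and 7272 lower (1168 and 4062 among those with a protein name). The count was 5209 at an adjusted p under 0.01 with at least a 2-fold change. It was 5666 without control replicate 1 and 7722 without control replicate 2.

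**Figure D2:**
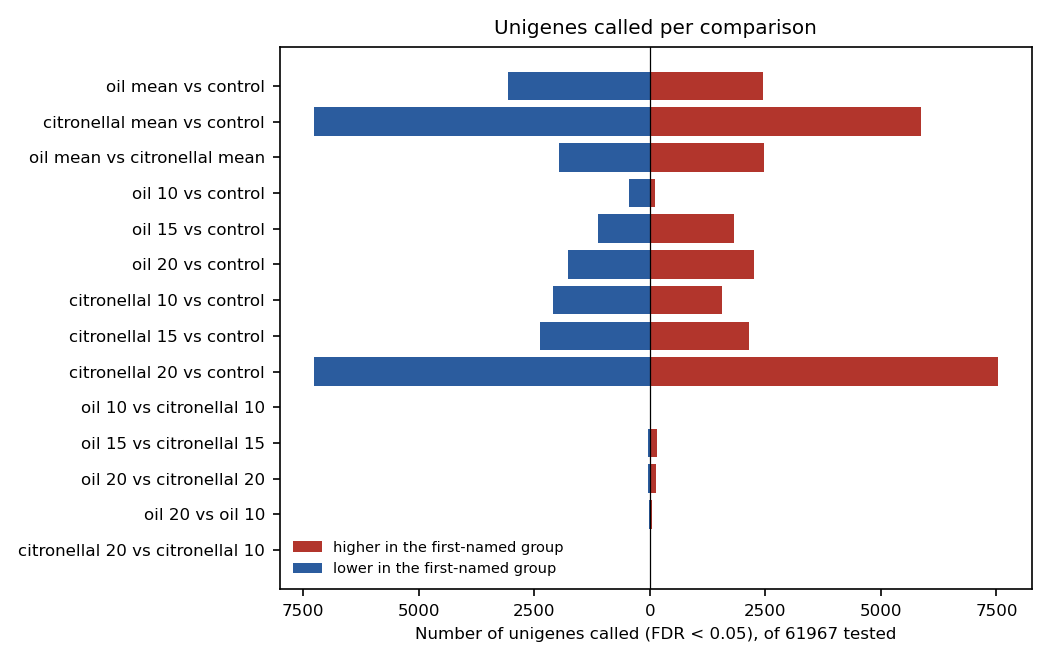
Number of unigenes called of 61967 tested (adjusted p under 0.05, edgeR's quasi-likelihood test) in each of the 14 comparisons, lower to the left and higher to the right. Citronellal against control has 13146 and the oil 5510, but 8886 and 8750 when fitted apart.

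Lipid and yolk lists were called lower under citronellal as well. Of the fatty acid metabolism unigenes 136 of 311 fell and 9 rose (162 and 14 adjusted over the list alone), with a median log2 fold change of -1.04 (camera adjusted p = 2.05e-17, and adjusted p = 0.0454 with an estimated correlation). The elongase (Cluster-40802.106384) fell from 10.9 ± 7.56 to 0.588 ± 0.384 CPM (log2 fold change -4.26, and -3.61 without control replicate 1), while elongase 4 (Cluster-40802.29737) rose (log2 fold change 0.73, adjusted p = 0.00175). Of the vitellogenin and yolk unigenes 27 of 36 fell and 0 rose (27 and 1 adjusted over the list alone), with a median of -3.16 (camera adjusted p = 4.71e-19, and adjusted p = 0.0454 with an estimated correlation). Camera called 18 lists, 17 of them lower, and 3 calls held with an estimated correlation: fatty acid metabolism, vitellogenin and yolk, and carboxylesterase and cholinesterase. Of the 31818 described unigenes 16.7% were lower, and against these alone camera called 14 lists, none of them with an estimated correlation (smallest adjusted p = 0.131). In these libraries the named share of counts and GC content were below control, and citronellal 20 mg/mL replicate 1 had the fewest unigenes counted.

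Lists of enzymes and transporters that act on foreign compounds were called lower under citronellal. Cytochrome P450 4V2 (Cluster-40802.79228) fell from 23.9 ± 11.5 to 3.05 ± 0.694 CPM (log2 fold change -2.98, adjusted p = 3.28e-07), a glutathione S-transferase (Cluster-40802.81060) fell from 30.8 ± 8.83 to 8.29 ± 1.78 CPM, an acetylcholinesterase (Cluster-40802.101384) had a log2 fold change of -3.62 (-2.84 without control replicate 1), and the canalicular multispecific organic anion transporter (Cluster-40802.40657) fell from 105 ± 39.4 to 10.2 ± 6.12 CPM. In the cytochrome P450 list 96 of 380 fell and 2 rose (101 and 5 adjusted over the list alone), and in the glutathione S-transferase list 22 of 63 fell and 1 rose (24 and 2 adjusted over the list alone). By camera, adjusted p = 5.42e-08 and 1.85e-06, and adjusted p = 0.316 and 0.124 with an estimated correlation. Within the carboxylesterase and cholinesterase list 44 of 93 fell and 0 rose (48 and 1 adjusted over the list alone), and within the sulfotransferase list 48 of 157 fell and 1 rose (54 and 1 adjusted over the list alone). For these lists, camera adjusted p = 3.16e-15 and 5.42e-08, and adjusted p = 0.0454 and 0.176 with an estimated correlation. Of the aldehyde and alcohol dehydrogenase unigenes 40 of 126 fell and 1 rose (46 and 2 adjusted over the list alone), and of the ABC transporter unigenes 84 of 313 fell and 9 rose (89 and 10 adjusted over the list alone). Their camera adjusted p = 8.86e-07 and 0.000544, and adjusted p = 0.124 and 0.154 with an estimated correlation. Against described unigenes alone the ABC list did not pass (camera adjusted p = 0.0524), and the carboxylesterase and cholinesterase list had adjusted p = 0.138 with an estimated correlation. The rise with the smallest adjusted p in the ABC list was named THO complex subunit 7 (Cluster-40802.71887), by name an mRNA export factor.

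Lists of receptors, channels and tissues were called lower too, TRP channels excepted. Glutamate receptor kainate 3 (Cluster-40802.14072) fell from 26.6 ± 2.64 to 2.08 ± 0.988 CPM (log2 fold change -3.70, SE 0.33, adjusted p = 1.49e-06), the Shaker potassium channel (Cluster-40802.41875) fell from 11.4 ± 3.65 to 3.41 ± 1.48 CPM. Dopamine receptor 2 (Cluster-32648.0) had a log2 fold change of -2.06. Against that direction an acetylcholine receptor subunit (Cluster-40802.64964) rose (log2 fold change 0.78, adjusted p = 0.00358). Within the ligand-gated ion channel list 25 of 61 fell and 5 rose (29 and 5 adjusted over the list alone), and within the voltage-gated ion channel list 15 of 40 fell and 1 rose (19 and 1 adjusted over the list alone). For these lists, camera adjusted p = 2.3e-06 and 0.00032, and adjusted p = 0.124 and 0.124 with an estimated correlation. Of the monoamine and muscarinic receptor unigenes 11 of 23 fell and 2 rose (12 and 3 adjusted over the list alone). This list's camera adjusted p = 0.0022, and adjusted p = 0.154 with an estimated correlation. TRP channels had 1 lower and 0 higher of 8 (1 and 0 adjusted over the list alone), camera adjusted p = 0.164, where the fall was the TRP-gamma protein (Cluster-40802.45824, adjusted p = 0.00631, but 0.0704 without control replicate 1). Myosin-16 fell from 20.9 ± 3.43 to 5.05 ± 1.58 CPM and cathepsin B fell from 119.7 ± 66.8 to 10.3 ± 3.28 CPM. Of the cuticle protein and chitin metabolism unigenes 69 of 207 fell and 9 rose (72 and 10 adjusted over the list alone), and of the muscle contractile protein unigenes 36 of 97 fell and 5 rose (42 and 8 adjusted over the list alone). Their camera adjusted p = 2.71e-08 and 8.86e-07, and adjusted p = 0.0721 and 0.154 with an estimated correlation. Among salivary protein families unigenes 105 of 418 fell and 8 rose (108 and 9 adjusted over the list alone), and among cathepsin and legumain (midgut proteases) unigenes 7 of 35 fell and 0 rose (7 and 0 adjusted over the list alone). The lists' camera adjusted p = 5.81e-06 and 0.0311, and adjusted p = 0.124 and 0.355 with an estimated correlation. The cathepsin list did not pass against described unigenes alone (camera adjusted p = 0.232).

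Cytosolic ribosomal proteins were the list called higher under citronellal: 0 of 154 fell and 24 rose (0 and 15 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 2.95e-07, and adjusted p = 0.428 with an estimated correlation), and 60S ribosomal protein L32 (Cluster-18706.0) rose (log2 fold change 1.28, adjusted p = 0.00407). Antioxidant enzymes were called lower, and 26 of 109 fell and 8 rose (28 and 11 adjusted over the list alone), camera adjusted p = 0.00775, and adjusted p = 0.149 with an estimated correlation, as were apoptosis and autophagy unigenes, where 30 of 189 fell and 5 rose (27 and 4 adjusted over the list alone), camera adjusted p = 0.0311, and adjusted p = 0.316 with an estimated correlation. Neither list passed against described unigenes alone (camera adjusted p = 0.172 and 0.42). The antioxidant fall with the smallest adjusted p was named chitinase 2 (Cluster-40802.55706), by name an enzyme of chitin breakdown. Heat shock proteins had 28 lower and 12 higher of 128 (30 and 15 adjusted over the list alone), camera adjusted p = 0.256, and alpha-crystallin A (Cluster-40802.41586) fell within them (log2 fold change -2.30). Serpins and Kunitz inhibitors had 38 lower and 10 higher of 218 (39 and 12 adjusted over the list alone), camera adjusted p = 0.256. Defensins and immune effectors had 35 lower and 15 higher of 194 (36 and 15 adjusted over the list alone), camera adjusted p = 0.256, with Toll-like receptor 2 (Cluster-40802.43833) lower (log2 fold change -3.03, and -2.08 without control replicate 1) and the called rise of smallest adjusted p named as a zinc finger protein (Cluster-40802.44446), by name a DNA-binding protein. Ferritin and heme handling had 3 lower and 0 higher of 17 (3 and 0 adjusted over the list alone), camera adjusted p = 0.311, and the mitochondrial respiratory chain had 49 lower and 43 higher of 360 (55 and 46 adjusted over the list alone), camera adjusted p = 0.752. The proteasome list had 20 lower and 17 higher of 139 (22 and 24 adjusted over the list alone), camera adjusted p = 0.812, and aminoacyl-tRNA synthetases had 11 lower and 3 higher of 110 (10 and 3 adjusted over the list alone), camera adjusted p = 0.888. Both had a median above 0 (0.04 and 0.02) that turned below 0 with RLE scaling, as did that of all tested unigenes (0.01 to -0.03). Histones and DNA replication had 12 lower and 4 higher of 72 (12 and 4 adjusted over the list alone), camera adjusted p = 0.511. Of the lists camera did not call, fry called 6 lower: heat shock (adjusted p = 0.00119), immune (0.00142), mitochondrial (0.00392), TRP (0.023), histone (0.0278) and serpin (0.0288). It did not call the ribosomal list (0.051). Median, mean and camera's direction differed in sign under citronellal for the proteasome, serpin, aminoacyl-tRNA synthetase and histone lists.

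**Figure D3:**
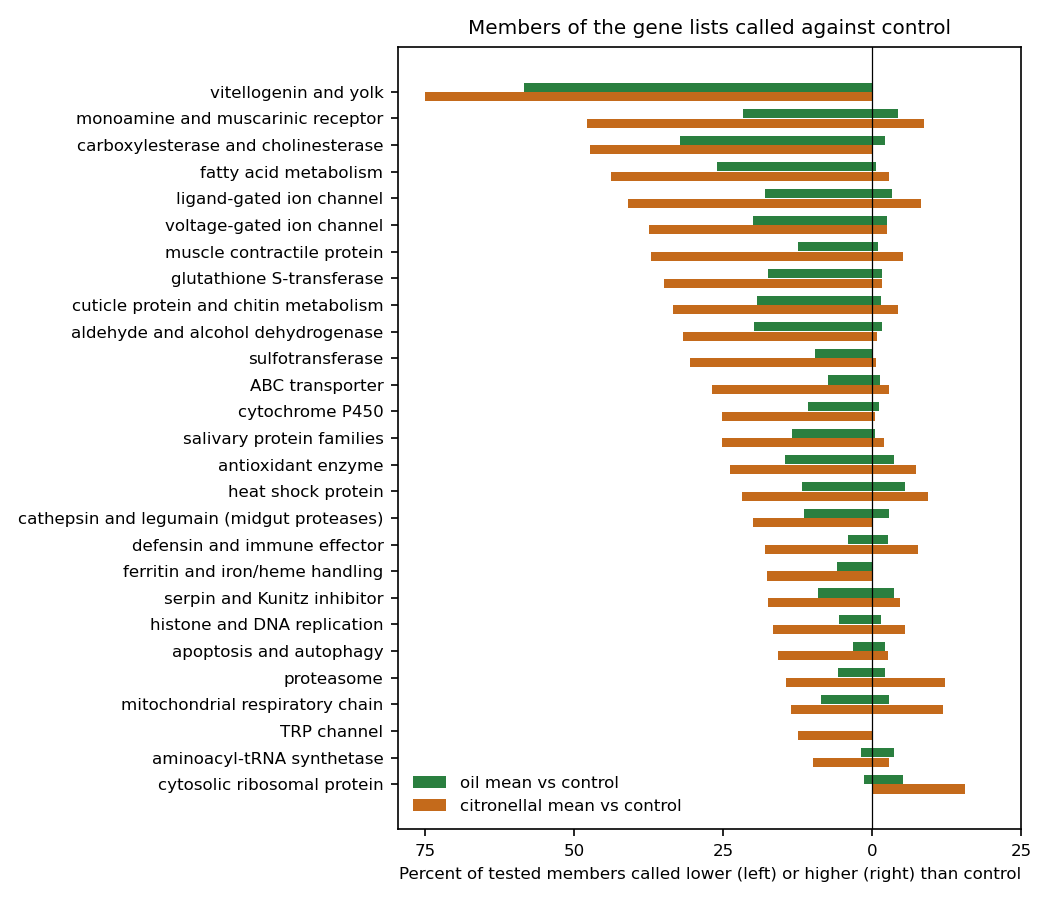
Percent of the tested members of each of the 27 lists called lower (left) and higher (right) for the oil and for citronellal against control, as bars. In the vitellogenin and yolk list 21 of 36 members were lower under the oil and 27 of 36 under citronellal.

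The transcripts called in both comparisons moved the same way: 1959 were higher and 2695 lower under both compounds, and 0 were called in opposite directions. Fatty acid synthase, vitellogenin-2, cytochrome P450 4V2 and glutamate receptor kainate 3 were among those lower in both. Lists drawn independently would share 232 higher and 359 lower unigenes. Both comparisons use the same 3 controls, which by itself makes fold changes alike. Unchanged groups simulated against these controls had the same sign for 76.8% of unigenes (80.2% observed). Their correlation across unigenes was 0.746 (highest of 20 simulations 0.758, observed 0.759). Unigenes are not independent replicates but were simulated as such, so the simulated ranges here and below may be too narrow. The covariance of the log2 fold changes was 0.929 against 0.379 simulated. Part of the excess of shared calls over independent lists may come from the shared controls. In 6 further fits, chosen after seeing the data, 1 control library served 1 compound and the other 2 the other. The lone library was assumed to vary like the other groups. The covariance was then 0.391 to 0.736, against 0.0201 to 0.0503 for simulated unchanged groups. The sign was the same for 63.9% to 71.6% of unigenes, against 49.8% to 50.4% simulated. In these fits 4 to 176 unigenes were higher and 104 to 865 lower under both, with 0 or 1 in opposite directions, where independent lists would share 0.813 to 10.9 higher and 11.2 to 59.4 lower.

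**Figure D4:**
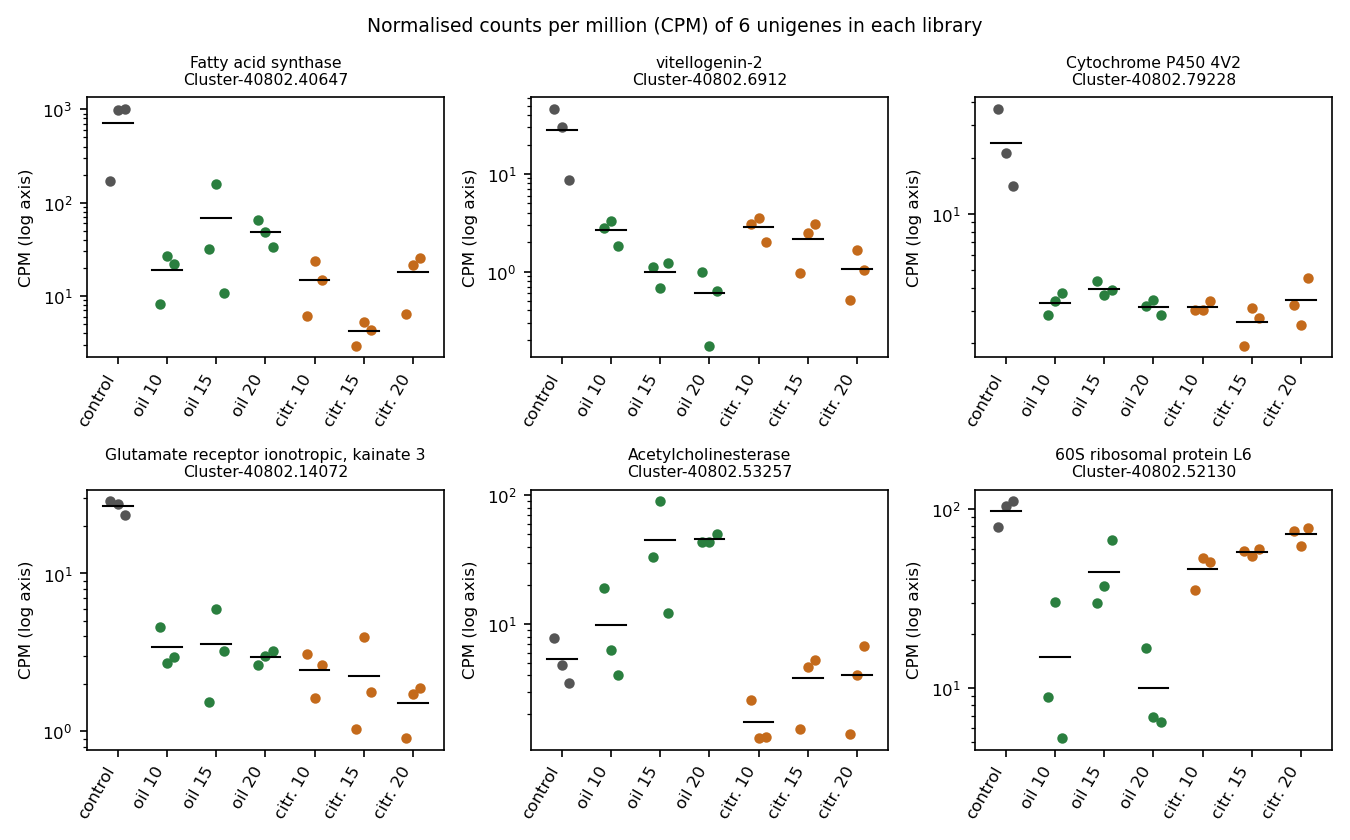
CPM on a log axis for 6 unigenes, 1 point per library by group, with the group mean as a horizontal bar. Over the 3 concentrations fatty acid synthase averages 45.2 CPM under the oil and 12.3 under citronellal, against 720.4 in control.

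Of the 8 largest differences with higher levels under the oil than under citronellal, 3 were transcripts of salivary proteins. A secreted salivary protein (Cluster-40802.97780) averaged 24.8 ± 25.3 CPM under the oil and 0.529 ± 0.409 CPM under citronellal (log2 fold change 4.83, SE 0.57, adjusted p = 0.00065), with 1.94 ± 1.31 CPM in control. A secreted salivary gland peptide (Cluster-40802.52045) averaged 746 ± 801 CPM under the oil and 11.9 ± 9.85 CPM under citronellal (log2 fold change 4.46, or 5.18 without citronellal 10 mg/mL replicate 2, adjusted p = 0.00467), but 11 ± 9.34 CPM at 10 mg/mL of the oil, with 41.1 ± 20.3 CPM in control. Another salivary gland peptide (Cluster-40802.46098) averaged 27.2 ± 24.2 CPM under the oil, 1.85 ± 1.22 under citronellal and 9.32 ± 4.75 in control (log2 fold change 3.75, adjusted p = 0.00065). Acetylcholinesterase (Cluster-40802.53257) averaged 33.5 ± 27.1 CPM under the oil, 3.21 ± 2.03 under citronellal and 5.37 ± 2.22 in control (log2 fold change 3.17, adjusted p = 0.00134). Ornithine decarboxylase (Cluster-40802.54492) averaged 200.3 ± 168 CPM under the oil, 23.1 ± 16.6 under citronellal and 62.5 ± 21.6 in control (adjusted p = 0.00425). For each of these unigenes, most libraries at 10 mg/mL of the oil lay within or below the control range.

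The other largest differences in that direction were inositol oxygenase (Cluster-40802.40365, log2 fold change 4.04), a GGY domain protein (Cluster-40802.85725, 3.16) and a secreted mucin (Cluster-40802.74843, 3.14). All 8 kept their call without any single library, although none had all 9 oil libraries above all 9 citronellal libraries. Without citronellal 15 mg/mL replicate 2 the log2 fold change was 5.16 for inositol oxygenase and 4.38 for the mucin, and without oil 15 mg/mL replicate 2 it was 2.96 for inositol oxygenase. In the other direction, 60S ribosomal protein L6 (Cluster-40802.52130) averaged 23.2 ± 20.4 CPM under the oil and 58.6 ± 12.9 CPM under citronellal (log2 fold change -1.61, SE 0.28, adjusted p = 0.00525), and an insulin-like growth factor binding protein-related protein (Cluster-40802.48324) averaged 93.2 ± 103 CPM under the oil and 202 ± 131 CPM under citronellal against 713 ± 87.1 CPM in control (adjusted p = 0.0142). These kept their call without any single library. The 6 others lost it without at least 2 libraries, and their highest adjusted p, each without oil 10 mg/mL replicate 1, ran from 0.0553 to 0.124. They were protein TAR1 (log2 fold change -2.30, and -1.54 without citronellal 20 mg/mL replicate 3), an X-element polymerase, initiation factor IF-2, the ubiquitin ligase subunit sconC, a hydroxysteroid dehydrogenase and an Adf-1-like transcription factor.

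Between the means of the compounds 4448 unigenes were called, 2474 higher and 1974 lower under the oil, and among those with a protein name 1197 were higher and 668 lower. The count was 450 at an adjusted p under 0.01 with at least a 2-fold change, 7964 with DESeq2, and 2258 without citronellal 20 mg/mL replicate 1 and 15 mg/mL replicate 1. Leaving out 1 library at a time, it was 1901 and 2345 without citronellal 10 mg/mL replicates 2 and 3, 2347, 7415 and 2545 without 15 mg/mL replicates 1, 2 and 3, and 6806 without 20 mg/mL replicate 2. It was 1581 without oil 10 mg/mL replicate 1, 1536 without oil 15 mg/mL replicate 2, and 2677, 2546 and 2815 without oil 20 mg/mL replicates 1, 2 and 3.

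Of the 16 lists that camera called between the compounds, 15 were higher under the oil. Fatty acid metabolism had 2 lower and 37 higher of 311 (4 and 47 adjusted over the list alone), camera adjusted p = 0.000249, salivary protein families had 2 lower and 35 higher of 418 (4 and 41 adjusted over the list alone), camera adjusted p = 0.033, and sulfotransferases had 0 lower and 19 higher of 157 (0 and 19 adjusted over the list alone), camera adjusted p = 0.000641. With an estimated correlation each had adjusted p = 0.417. ABC transporters had 3 lower and 25 higher of 313 (3 and 30 adjusted over the list alone), camera adjusted p = 0.00462, cytochrome P450 unigenes had 2 lower and 26 higher of 380 (2 and 26 adjusted over the list alone), camera adjusted p = 0.0264, and glutathione S-transferases had 0 lower and 7 higher of 63 (0 and 9 adjusted over the list alone), camera adjusted p = 0.000641. With an estimated correlation P450 had adjusted p = 0.632 and the others 0.417. Cytosolic ribosomal proteins were called lower under the oil than under citronellal, with 1 lower and 0 higher of 154 (1 and 0 adjusted over the list alone), camera adjusted p = 0.0323, and adjusted p = 0.736 with an estimated correlation. None of the 16 calls held with an estimated correlation. Of the lists named here, fry did not call salivary families and sulfotransferases (adjusted p = 0.0516 for both), P450 (0.288) or ribosomal proteins (0.505). Against described unigenes alone camera called 9, and the salivary and cytochrome P450 lists did not pass (camera adjusted p = 0.127 and 0.115). Median, mean and camera's direction differed in sign for the proteasome, cathepsin and histone lists, and the histone median of -0.02 rose above 0 without rRNA unigenes, as did that of all tested unigenes. Camera called 6 without citronellal 20 mg/mL replicate 1 and 15 mg/mL replicate 1, and 8 without citronellal 15 mg/mL replicate 1.

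Some of these transcripts were also called at matched concentrations. The secreted salivary protein (Cluster-40802.97780) differed by a log2 fold change of 2.48 (95% interval 0.41 to 4.54) at 10 mg/mL, which was not called, 6.45 (95% interval 4.24 to 8.66) at 15 mg/mL (adjusted p = 0.0263) and 5.57 (95% interval 3.50 to 7.63) at 20 mg/mL (adjusted p = 0.0305). The salivary gland peptide Cluster-40802.46098 was higher under the oil at 15 mg/mL (adjusted p = 0.0462) and 20 mg/mL (adjusted p = 0.0419). A small heat shock protein (Cluster-40802.56614) was higher at 15 mg/mL (log2 fold change 2.05, adjusted p = 0.0108) and 20 mg/mL (adjusted p = 0.0153). 60S ribosomal protein L6 (Cluster-40802.52130) was lower under the oil at 20 mg/mL, with a log2 fold change of -2.84 (95% interval -3.93 to -1.75, adjusted p = 0.0339), with -0.36 (95% interval -1.37 to 0.65) at 15 mg/mL. For fatty acid synthase (Cluster-40802.40647) the difference was 0.35 (95% interval -1.47 to 2.17) at 10 mg/mL, 4.02 (95% interval 1.97 to 6.08) at 15 mg/mL (adjusted p = 0.0797) and 1.45 (95% interval -0.40 to 3.30) at 20 mg/mL, and for cytochrome P450 4V2 (Cluster-40802.79228) it was 0.08 (95% interval -0.58 to 0.74), 0.60 (95% interval -0.06 to 1.27) and -0.11 (95% interval -0.77 to 0.55). The salivary protein had 3.16 without citronellal replicate 2 and 1.34 without oil replicate 2 at 10 mg/mL, 5.02 without oil replicate 2 at 15 mg/mL, and 6.27 without citronellal replicate 3 at 20 mg/mL. The gland peptide went from 3.81 to 2.72 at 15 mg/mL without oil replicate 2, and fatty acid synthase had there 2.35 and 4.62 without oil replicates 2 and 3. None of the calls named here was kept without each library in turn. At 15 mg/mL the salivary protein lost its call without citronellal replicates 1 or 3 or oil replicate 2 (adjusted p up to 0.116), the salivary gland peptide in each case but that without oil replicate 3 (up to 0.236) and the heat shock protein without citronellal replicate 1 (0.0602). At 20 mg/mL leaving out citronellal replicate 1, citronellal replicate 3 or oil replicate 2 ended all 4 calls, as leaving out oil replicate 1 did for both salivary transcripts and oil replicate 3 for the gland peptide and L6. The adjusted p reached 0.149 for the salivary protein, 0.167 for the gland peptide, 0.0841 for the heat shock protein and 0.148 for L6. Fatty acid synthase at 15 mg/mL was called without oil replicate 3 and by DESeq2.

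Counts at matched concentrations were 0 at 10 mg/mL, 185 at 15 mg/mL (154 higher and 31 lower under the oil) and 175 at 20 mg/mL (136 higher and 39 lower). The 0 at 10 mg/mL is edgeR's, beside 2246 unigenes at an unadjusted p under 0.05, 46 called by DESeq2 and 3 with no low-count filter. The 95% interval of the difference lay within 1 log2 unit of 0 for 22.7%, 18.5% and 16.6% of unigenes at 10, 15 and 20 mg/mL, so that for most unigenes a 2-fold difference was not excluded. At 15 mg/mL the count was 0, 1055 and 10 without citronellal replicates 1, 2 and 3, and 35, 3 and 413 without oil replicates 1, 2 and 3. At 20 mg/mL it was 5, 2671 and 23 without citronellal replicates 1, 2 and 3, and 35, 9 and 58 without oil replicates 1, 2 and 3. DESeq2 called 2122 at 15 mg/mL and 3194 at 20 mg/mL.

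Each concentration was also set against control. Fatty acid synthase (Cluster-40802.40647) was lower at all 6, with log2 fold changes of -5.25 (adjusted p = 0.0282), -3.41 (adjusted p = 0.0478) and -3.88 (adjusted p = 0.0242) for the oil at 10, 15 and 20 mg/mL, and -5.60 (adjusted p = 0.00857), -7.44 (adjusted p = 0.00295) and -5.33 (adjusted p = 0.00221) for citronellal. Vitellogenin-2 (Cluster-40802.6912) had 2.65 ± 0.753, 0.999 ± 0.284 and 0.599 ± 0.412 CPM (SD, n = 3) under the oil, all below control by the test (largest adjusted p = 0.0122). Cu-Zn superoxide dismutase (Cluster-40802.52850) was lower at 15 and 20 mg/mL of the oil (adjusted p = 0.0187 and 0.00554) and had -1.45 (adjusted p = 0.215) at 10 mg/mL. The small heat shock protein (Cluster-40802.56614) rose at 15 and 20 mg/mL of the oil, with log2 fold changes of 1.80 (adjusted p = 0.00126) and 1.72 (adjusted p = 0.00117), and had -0.13 (adjusted p = 0.883) at 10 mg/mL. Microplusin (Cluster-40802.64357) rose at 20 mg/mL of citronellal with a log2 fold change of 3.22 (adjusted p = 0.000835), but 2.25 without citronellal replicate 1, and had 1.61 (adjusted p = 0.0703) at 10 mg/mL. Without single libraries, the calls of fatty acid synthase under the oil were lost in 5 of 6 cases each, with adjusted p up to 0.138 at 10 mg/mL (without oil replicate 2), 0.19 at 15 mg/mL (without oil replicate 1) and 0.107 at 20 mg/mL (without oil replicate 2). The log2 fold change at 15 mg/mL was -5.08 without oil replicate 2. The calls were kept without control replicate 3, oil replicate 2 and control replicate 1, respectively. Vitellogenin-2 at 10 mg/mL lost its call without control replicate 1 or any oil library (up to 0.0945), and superoxide dismutase at 15 mg/mL without control or oil replicates 1 or 2 (up to 0.105), while the other calls named here were kept.

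For the oil, 566 unigenes were called at 10 mg/mL (121 higher, 445 lower), 2952 at 15 mg/mL (1828 higher, 1124 lower) and 4029 at 20 mg/mL (2262 higher, 1767 lower). At 10 mg/mL the count was 74, 45 and 33 without oil replicates 1, 2 and 3, and 49 and 116 without control replicates 1 and 2. At 15 mg/mL it was 1063, 1968 and 1554 without oil replicates 1, 2 and 3, and 926, 1089 and 1702 without control replicates 1, 2 and 3. At 20 mg/mL it was 1449 and 1497 without oil replicates 1 and 2, and 1269, 1803 and 2652 without control replicates 1, 2 and 3. For citronellal, 3674 were called at 10 mg/mL (1571 higher, 2103 lower), 4519 at 15 mg/mL (2150 higher, 2369 lower) and 14797 at 20 mg/mL (7529 higher, 7268 lower). At 10 mg/mL the count was 931, 538 and 920 without citronellal replicates 1, 2 and 3, and 363 and 1273 without control replicates 1 and 2. At 15 mg/mL it was 1028, 7040 and 1336 without citronellal replicates 1, 2 and 3, 703 and 1353 without control replicates 1 and 2, and 51 with only the groups compared in the fit. At 20 mg/mL it was 7521 without citronellal replicate 1, and 7985 and 9514 without control replicates 1 and 2. With RLE scaling, the calls were 1135 higher and 2332 lower for citronellal at 10 mg/mL, and 1432 higher and 2583 lower at 15 mg/mL.

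Between the highest and lowest concentration, the small heat shock protein (Cluster-40802.56614) was higher at 20 than at 10 mg/mL of the oil (log2 fold change 1.85, adjusted p = 0.0133), as were the pogo element protein (Cluster-40802.11590, 3.31, adjusted p = 0.029) and cathepsin L1 (Cluster-40802.11135, 5.32, adjusted p = 0.0132). The count was 58 (38 higher and 20 lower at 20 mg/mL), and 194, 0 and 0 without replicates 1, 2 and 3 of the lowest concentration, 6, 10 and 23 without those of the highest, and 768 with DESeq2. Cathepsin L1 had a log2 fold change of 4.06 without replicate 3 of the highest, and the pogo element protein 3.98 without replicate 1 of the lowest. The 3 calls named here ended without replicate 2 or 3 of the lowest concentration, with adjusted p up to 0.143, 0.225 and 0.139, and that of the pogo element also without replicate 1 or 2 of the highest. For citronellal, edgeR called 0 unigenes, beside 1032 called by DESeq2, 13 with no low-count filter and 8 with only the groups compared in the fit. At an unadjusted p under 0.05 there were 8426 of 61967 unigenes, a share above 0.05. Leaving out citronellal 20 mg/mL replicate 2 gave 504 calls. The 95% interval lay within 1 log2 unit of 0 for 21.2% of unigenes for the oil and 18.4% for citronellal.

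At an unadjusted p under 0.05 by DESeq2, the authors' deposited table gives 11100, 14522 and 15970 unigenes for the oil at 10, 15 and 20 mg/mL against control, and 16735, 13643 and 20047 for citronellal.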

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

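The tests of sequencing depth, of a swapped library and of the mitochondrial share were chosen only after the results they bear on were seen, as were the fits that leave out citronellal 20 mg/mL replicate 1 or rRNA unigenes. The way splits were counted for the compound means was also set after a first result: a split was counted once however the concentrations fell within it.

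The change from control differed between the oil and citronellal for 4448 unigenes over the 3 concentrations, among them a secreted salivary protein (Cluster-40802.97780) and a salivary gland peptide (Cluster-40802.52045). At 15 mg/mL it differed for 185 unigenes and at 20 mg/mL for 175. The difference itself was tested in each case, since the control cancels between the compounds.

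Unigenes with a protein name tended to be lower in treated libraries and those without one higher. Their median log2 fold changes were -0.15 and 0.06 under the oil, and -0.19 and 0.11 under citronellal. Within strata of equal length and expression the difference was -0.25 for the oil (95% bootstrap interval -0.27 to -0.23) and -0.31 for citronellal (-0.34 to -0.29), which argues against length and expression level as the whole cause. Genomic DNA in treated libraries would leave named and unnamed unigenes alike among those with the fewest reads per kilobase. There the difference was -0.23 for citronellal (-0.28 to -0.18) and -0.11 for the oil (-0.15 to -0.07), with a bound of -0.1 set beforehand. These intervals resample unigenes and hold no spread between libraries, so DNA stays open for both. A response to treatment and different handling of the control libraries may each contribute and cannot be told apart, as the labels give no batch.

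Citronellal 20 mg/mL replicate 1 had counts on 72593 unigenes, fewer than any other library. Its total count, 15278180, lay within the range of the others (15139536 to 17240128), which argues against depth. With rRNA unigenes left out and every library thinned to 1 depth it still had 72472, against 92840 to 109984 in the others, which argues against rRNA reads as the whole cause. Its highest correlation was 0.912 within its group and 0.893 outside it. This cannot tell a swap, as its group mates correlated best with other groups. A swap, degraded RNA and a stronger response may each be the source, and no value here decides between them.

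GC content of the reads was lower by 2.73 percentage points in treated libraries, a change of -2.73 (95% bootstrap bounds of the drop 2.16 and 3.38). Had the added mitochondrial reads held no G or C, those counted would give a drop of at most 0.985 points. Reads not counted also entered the GC content, so this cannot decide. The mitochondrial share, a different mix of transcripts after treatment and a difference in library preparation may each be the source. The last cannot be told apart from treatment, since no batch is given.

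For the compound means, only the real one of 100 splits of the libraries compared gave as many called unigenes. It gave 8750 for the oil against control (highest other 1202), 8886 for citronellal (1408) and 3146 for the oil against citronellal (10). This argues against chance division of the libraries, but not of ticks if replicates are technical. The fits used only the libraries compared, 61967 unigenes and no robust dispersion. Their counts thus differ from the main ones, and from those with only the groups compared, where unigenes were refiltered. For 3 libraries against 3, the 10 splits are too few for a share under 0.05. Against control, the real value and the highest other were 1138 and 2 for the oil at 10 mg/mL, 3715 and 1 at 15 mg/mL, and 6189 and 0 at 20 mg/mL. For citronellal they were 8301 and 0 at 10 mg/mL, 23 and 1 at 15 mg/mL, and 4366 and 0 at 20 mg/mL. Between the compounds they were 0 and 8 at 10 mg/mL, where all 10 splits gave as many, 3 and 1 at 15 mg/mL, and 25 and 2 at 20 mg/mL. Between 20 and 10 mg/mL they were 6 and 5 for the oil, and 8 and 2 for citronellal.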

How the results depend on the processing

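The fits without citronellal 20 mg/mL replicate 1, without it and 15 mg/mL replicate 1, without rRNA unigenes, with separate controls for each compound (values in the report), and with camera among described unigenes alone were chosen after seeing the data. Of 153 values for named unigenes over the compound means, 98 kept their call in each fit run on them and 99 without each library in turn, and none changed direction there. Values of single unigenes were not recomputed with separate controls or the stricter threshold, and 2 had no test with a mean CPM of at least 1 and 1 without rRNA unigenes. Falls kept their call for 33 of 34 under the oil and 35 of 36 under citronellal, but rises for 5 of 33 and 15 of 34 (2 of 21 oil rises named from a list only), and 8 of 8 higher and 2 of 8 lower values did between the compounds. Of 35 values at single concentrations 24 were called, of which 9 kept their call in these fits and without each library. Among the others, leaving out 1 library turned the direction for fatty acid synthase between the compounds at 10 mg/mL (log2 fold change from -0.016 without citronellal replicate 1 to 0.867) and for cytochrome P450 4V2 at 10 mg/mL (from -0.013 without oil replicate 3 to 0.166) and 20 mg/mL (from -0.231 to 0.148, with 0.029 and 0.148 without oil or citronellal replicate 3), none of them called. With RLE scaling or without rRNA unigenes no count moved by over 1.5 times, although with RLE the share of higher calls fell for citronellal at 10 and 15 mg/mL. Totals were 15139536 to 17240128, and 2% of simulated 2-fold changes were called for the oil mean, with 200 unigenes changed. Depth, the number of changed unigenes and the spread between libraries (common biological coefficient of variation 48.6%) were not varied separately, so their shares in this limit are not known. Without 1 control library the oil mean gave 1498 to 3495 calls, against 4198 to 5580 without 1 oil library. Where a value below differs, fewer libraries or unigenes in the fit or a stricter threshold are part of the alternative itself. Beyond that the cause was not tested.

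With DESeq2 the count was 7964 for the oil mean against the citronellal mean, 2758, 5416 and 6714 for the oil at 10, 15 and 20 mg/mL against control, and 6933 and 7899 for citronellal at 10 and 15 mg/mL. Between the compounds it was 46, 2122 and 3194 at 10, 15 and 20 mg/mL, and for 20 against 10 mg/mL it was 768 for the oil and 1032 for citronellal. With an adjusted p under 0.01 and at least a 2-fold change, the means gave 1713 for the oil, 5209 for citronellal and 450 between them. The single concentrations gave 65, 759 and 1138 for the oil and 553, 729 and 6046 for citronellal, and between the compounds 1 at 15 mg/mL and 3 at 20 mg/mL. The oil at 20 against 10 mg/mL gave 1. With an estimated correlation camera called 0, 3 and 0 lists for the oil, citronellal and their difference (15, 18 and 16 with the preset one), and fry called 17, 23 and 13. Against described unigenes alone camera called 13, 14 and 9, and 0, 0 and 0 with an estimated correlation.

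Without citronellal 20 mg/mL replicate 1 and 15 mg/mL replicate 1, the oil mean gave 9079, the difference of the compounds 2258 unigenes and 6 lists, the oil concentrations 2514, 5906 and 7299, citronellal 7255 at 10 and 8934 at 20 mg/mL, the matched pairs 57 at 15 and 86 at 20 mg/mL, and the oil at 20 against 10 mg/mL 391. Without the former library alone, the oil concentrations gave 1737, 4952 and 6134, citronellal 6219, 6801 and 7521, the matched pairs 504 and 5, and the oil at 20 against 10 mg/mL 167. With a mean CPM of at least 1 the matched pairs gave 327 at 15 and 430 at 20 mg/mL. With no low-count filter citronellal gave 2433 at 10 and 2756 at 15 mg/mL, the matched pairs 3, 420 and 523, and 20 against 10 mg/mL 162 for the oil and 13 for citronellal. With only the groups compared in the fit, the oil mean gave 9073, the oil concentrations 2358, 5140 and 7666, citronellal 9996, 51 and 6944, the matched pairs 3 at 15 and 81 at 20 mg/mL, and citronellal at 20 against 10 mg/mL 8.

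Leaving out 1 library at a time gave 1498 to 5580 for the oil mean, 5666 to 16202 for citronellal and 1536 to 7415 between them, with 13 to 18, 16 to 19 and 8 to 17 lists. The oil gave 33 to 528, 926 to 1968 and 1269 to 2754 at 10, 15 and 20 mg/mL, and citronellal 363 to 2553, 703 to 7040 and 7521 to 18537. The matched pairs gave 0 to 0, 0 to 1055 and 5 to 2671, and 20 against 10 mg/mL 0 to 194 for the oil and 0 to 504 for citronellal.

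The replicate block moved no count of calls by over 1.5 times and no count of lists (5253 unigenes for the oil mean, 12858 for citronellal, 3932 between them). Of the values for named unigenes over the compound means, 7 of 153 lost their call: the secreted salivary protein (adjusted p = 0.0655) and the GGY domain protein (0.0542) for the oil, bitisilin (0.0654) for citronellal, and TAR1 (0.076), the X-element polymerase (0.0686), initiation factor IF-2 (0.0549) and sconC (0.0664) between the compounds. At single concentrations the salivary gland peptide Cluster-40802.46098 between the compounds at 15 mg/mL lost its call (0.0563), and microplusin at citronellal 10 mg/mL gained one (0.0235). The correlation of deviations was over 0.1 for 13 of 63 same-number pairs (-0.255 to 0.273) and 17 of 126 different-number pairs (-0.259 to 0.258), and 10 of 21 libraries correlated best with their own number. Since not every same-number correlation was over 0.1, the numbers were not taken as pairing the libraries.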

Other observations

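The domain tests below were chosen after the results were seen. They used Fisher's exact test over 24626 tested unigenes with a Pfam domain, adjusted over 1848 tests, and unigenes are not independent of each other. Under citronellal, 134 of 263 unigenes with a Major Facilitator Superfamily domain, a family of membrane transporters, were called lower (adjusted p = 4.2e-33), where 17.2% of all unigenes with a domain were. So were 41 of 58 with a GNS1/SUR4 domain (adjusted p = 1.2e-16), the domain of fatty acid elongases, and 43 of 80 with a PDZ domain (adjusted p = 2.23e-11). Under the oil, where 7.26% were lower, it was 24 of 58 for GNS1/SUR4 (adjusted p = 8.4e-11), 52 of 263 for the Major Facilitator Superfamily (adjusted p = 3.59e-09), 15 of 27 for insulin-like growth factor binding proteins (adjusted p = 6.01e-09) and 19 of 65 for the chitin binding peritrophin domain (adjusted p = 5.17e-06).

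Zinc finger domains stood out among the rises under citronellal. Of 1641 unigenes with a C2H2 zinc finger, found in many DNA-binding proteins, 269 were called higher (adjusted p = 1.27e-29), where 7.87% of all unigenes with a domain were. It was 75 of 322 for the FYVE zinc finger (adjusted p = 2.2e-15).

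Among unigenes with no protein name, a few had large differences (CPM of the total count here, with no TMM factor). Cluster-40802.85895 was at 1 CPM or more in 6 of 9 oil libraries (239.6 to 585.5 CPM), in 0 of 9 citronellal libraries and in 0 of 3 controls. Cluster-40802.52931 was at 1 CPM or more in 2 of 3 controls (385.5 and 405.3 CPM), in 0 of 9 citronellal libraries and in 1 of 9 oil libraries, oil 10 mg/mL replicate 1 with 1871 CPM, where the next highest held 0.128 CPM.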
